A study of Drosophila melanogaster with 2 samples.

How the data were processed

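The samples were 2 biological replicates of whole mixed-sex embryos, 0 to 24 hours old, from a transgenic line with GFP at the C-terminus of *her*. Chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the labels. Groups and replicate numbers came from the sample labels. All samples fell into 1 group, so no comparison between groups, no paired fit and no test on regrouped samples was made. p-values describe regions or genes of 1 experiment and not a population of embryos.

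The authors deposited 4 lists on each of the builds dm6 and dm3: a relaxed list of peaks and background per replicate, a relaxed list of both replicates pooled, and the peaks that passed the IDR threshold. Per the deposited notes, each list was made from alignments together with the alignment of a control, and both replicates share that control. The aligner, the peak caller and their versions are not given in the sources used here. Peaks were called per replicate and on the pooled data, and all 3930 thresholded dm6 peaks were found in the pooled list with the same interval and summit. Every relaxed list holds 30000 regions, so its length is a fixed limit and says nothing of the number of bound sites. The deposited signal value per region is the authors' own, on a scale that the notes do not state. The deposited −log10 q-value was the same, 4.13, for every thresholded dm6 peak, so peaks were ranked by signal. In the thresholded dm6 list 24 entries share their interval with another entry and each has its own summit, so all were kept. The median width of the thresholded regions was 404 bp. Read counts per sample are not given in the sources used here. The precision of a share was described by its exact (Clopper-Pearson) 95% interval over regions or by the spread of random shifts, neither of which covers sequencing depth.

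Genes, transcripts and TSSs were taken from the Ensembl annotation, release 115, and sequence from the RefSeq genome assembly, both of which are Release 6 of the fly genome and hence dm6. All dm6 summits were checked to lie within the lengths of the arms 2L, 2R, 3L, 3R, 4 and X. No dm3 reference was used here, so dm3 lists were only counted. Coordinates are 1-based dm6 positions. Annotated transposable elements were left out of the genes.

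Summits per arm were compared with the arm's share of length by an exact binomial test for X and for 4. A gene was called bound when a thresholded summit lay within 1 kb of any of its TSSs, and X was compared with autosomes by Fisher's exact test. Replicate overlap was measured between lists of 500 to 16000 regions with summits within 200 bp, against 1000 circular shifts within each arm. Each summit was placed in the first class that applied among promoter (within 500 bp of a TSS), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and classes were compared with 1000 circular shifts. The 37 gene lists were compared with 10000 random lists of the same size, matched on decile of gene length and on number of TSSs (1, 2, or 3 and more), with two-sided permutation p values adjusted by the Benjamini-Hochberg method over the lists. Of the symbols in the lists 655 matched directly, 13 matched through an older symbol and 10 were left out because they did not match exactly 1 gene. Sequences were searched on both strands within 50 bp of the summit and in a window of the same width centred 350 bp to the left, with exact McNemar tests adjusted within each family (20 listed sequences and 2080 6-mers). The log2 ratio of a sequence compares its share at summits with that in the background, with 1 added to each count. Thresholds were an adjusted p of 0.05 for location classes, gene lists and sequences, and percentile 95 for the windows around *her*. The tests of arms, of X genes and of replicate overlap, and those in the closing section, used an unadjusted p of 0.05.

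The gene lists, the listed sequences, the tests described above, their thresholds and the alternatives were set before the data were examined, as was the rule by which the text names genes. Tests chosen later appear only in the closing section, which names them. That rule takes *her* and every member of the lists of sex determination, yolk protein and dosage compensation genes. It also takes the gene with the TSS nearest to each of the 10 strongest thresholded peaks, and up to 4 members of every other list with the strongest thresholded summit within 1 kb of a TSS. The alternatives used each replicate alone (its 3930 strongest regions), the 1965 strongest thresholded peaks, the 7860 strongest pooled regions, other distances to the TSS, other backgrounds and flanks, and other definitions of overlap. The closing section gives their effect.

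The tests of location, gene lists, sequences and replicate overlap were checked on simulated data, and the other tests were not. With 2000 simulated summits, 20 of 20 sets with summits planted at TSSs were called at promoters (median 2.92-fold) and 0 of 20 random sets. With binding simulated on 13945 genes, 35 of 40 lists planted at 3 times the base share passed the adjustment, and 10 of 200 random lists had an unadjusted p under 0.05. For sequences at 2000 simulated summits, 20 of 20 planted 6-mers were called, and 0 of 2080 were called without planting. These simulated summits lay at random positions and not mainly at promoters. The check therefore does not show how often base composition around a TSS alone gives a call. For replicate overlap, 70.25% of the 2000 summits were shared where 70% had been planted. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.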

Results

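Chromatin immunoprecipitation followed by sequencing was performed on whole *Drosophila melanogaster* embryos that carried a GFP-tagged copy of *her*. *her* (hermaphrodite) encodes a zinc-finger protein of the sex determination pathway. Embryos of both sexes were collected together at 0 to 24 hours of age, and the tagged protein was recovered with an antibody against GFP. The 2 biological replicates formed 1 group, so the data hold no contrast between conditions, and the results below describe where the protein was recovered on the genome. For each replicate a relaxed list of 30000 regions was deposited, together with a pooled relaxed list of 30000 regions and 3930 peaks that passed the irreproducible discovery rate (IDR) threshold on the dm6 build. The read depth behind the lists is not given in the sources used here, so no interval that needs it was computed. Each region carries a signal value, which is the authors' own and has no stated scale. It served to describe and rank regions within a list. In the thresholded list it ran from 90.8 to 9479, with a median of 138.

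The replicates shared most of their strong regions. Of the 500 strongest regions of replicate 1, 426 (85.2%) had a summit within 200 bp of one of the 500 strongest of replicate 2, against 0.151% ± 0.174 (SD over 1000 shifts) after random circular shifts of the summits within each arm. The share was 82.9% for the 1000 strongest, 76.0% for the 4000 strongest and 61.6% for the 16000 strongest, where shifts gave 4.60% ± 0.271. All 6 list depths gave p = 0.001 in the two-sided permutation test, the smallest that 1000 shifts can give. The gene nearest each of the 10 strongest peaks, named below, had nearly the same rank in both lists. *ush*, *fwd*, CG2790 and *Pka-C1* held ranks 1 to 4 in each. Across the 17004 regions of replicate 1 that matched a region of replicate 2, Spearman's rho of the signal was 0.663 and Pearson's r was 0.961. Across the 3914 thresholded peaks matched in both replicates, the values were 0.704 and 0.976. Those peaks had passed the IDR threshold, which weighs agreement between these same replicates. Their values therefore give no separate evidence of agreement. These correlations are across regions, which are not independent replicates, and Pearson's r is weighted towards the few strongest. Both replicates were called against the same control, so part of the shared regions may come from that control.

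**Figure D1:**
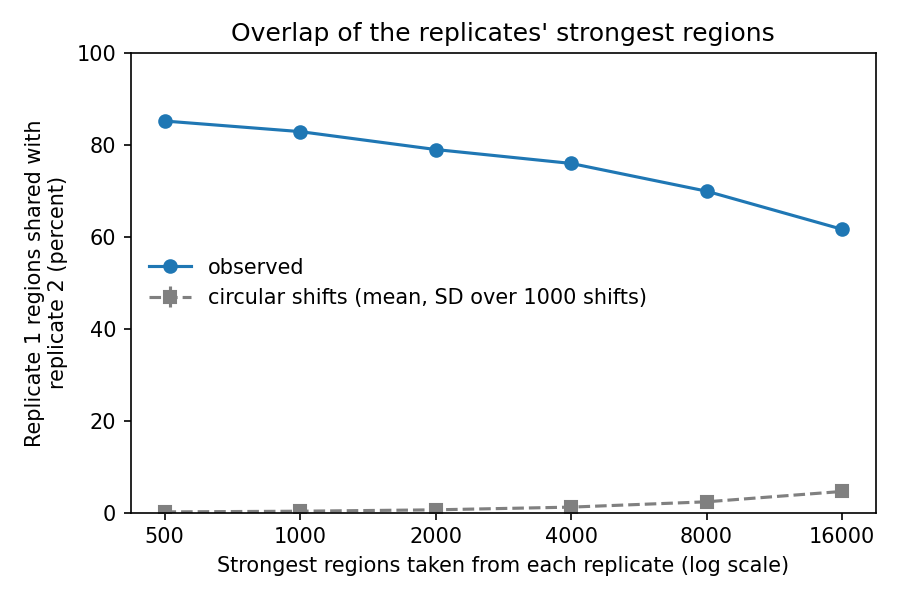
Share of the strongest regions of replicate 1 (vertical axis, percent) with a summit within 200 bp of an equally deep list from replicate 2, by number of regions taken (horizontal axis, log scale). Circles are observed values, which fall from 85.2% at 500 regions to 61.6% at 16000, and squares with bars are the mean and SD of 1000 circular shifts, which stay at or below 4.60%.

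The thresholded summits lay mostly at gene starts. Of 3930 summits, 2492 (63.4%, exact 95% interval 61.9 to 64.9) fell within 500 bp of an annotated transcription start site (TSS), against 13.7% ± 0.708 (SD over shifts) expected, a 4.64-fold excess. Introns held 1014 summits (25.8% against 39.3%) and intergenic sequence 333 (8.47% against 27.3%). Coding exons outside promoters held 15 summits (0.382% against 13.1%) and 3' UTRs 27 (0.687% against 5.01%). These 5 classes each had an adjusted p of 0.0014 (permutation test over 1000 shifts, two-sided, Benjamini-Hochberg), the smallest possible here. The 22 summits in 5' UTRs beyond the promoter window (0.56% against 0.779%, adjusted p = 0.147) and the 27 in other exons (0.687% against 0.825%, adjusted p = 0.413) did not pass this permutation test. Summits in 5' UTRs passed as fewer with a promoter window of 1000 bp (0.226-fold, adjusted permutation p = 0.0035) and against relaxed regions outside the peaks (0.39-fold, adjusted Fisher's exact p = 1.37e-06), but lay above expectation without passing with a window of 200 bp (1.19-fold) and with the 7860 strongest pooled regions (1.13-fold). Promoter summits sat a median of 36 bp upstream of the nearest TSS, and 67.3% of them were upstream. Against the 25123 relaxed regions that overlap no thresholded peak, in place of shifts, the promoter excess was 2.03-fold. It was 8.42-fold for a window of 200 bp around the TSS and 3.04-fold for 1000 bp.

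**Figure D2:**
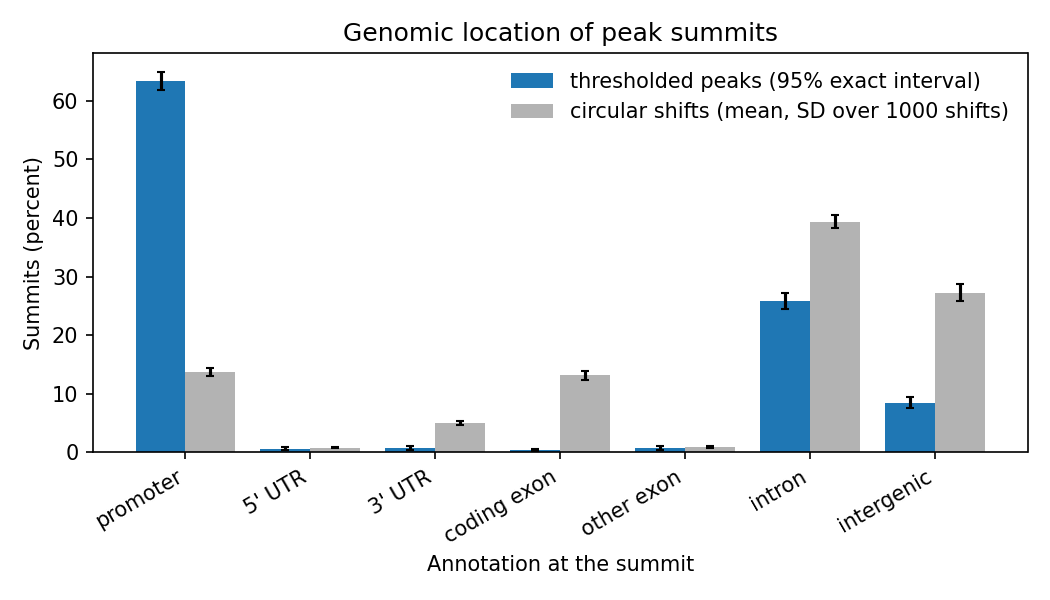
Percent of summits (vertical axis) in each annotation class (horizontal axis), for the 3930 thresholded peaks with exact 95% intervals and for 1000 circular shifts with their SD. Promoters held 63.4% of the summits against 13.7% in the shifts, and coding exons 0.382% against 13.1%.

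The strongest peak lay in *ush* (U-shaped, FBgn0003963), which encodes a zinc-finger cofactor of GATA factors. It spanned dm6 positions 489933 to 490886 on 2L, inside the gene (476220 to 540560, plus strand), with its summit at 490292 in an annotated 5' UTR, 543 bp upstream of the nearest TSS. Its signal was 9479. The next 9 peaks all had promoter summits between 35 and 78 bp upstream of a TSS. The peak at *fwd* (FBgn0004373), which encodes a phosphatidylinositol kinase, spanned 319426 to 320292 on 3L with a signal of 7003. The peak at CG2790 (FBgn0027599) spanned 24948068 to 24948787 on 2R with a signal of 6342. *Pka-C1* (FBgn0000273), the catalytic subunit of protein kinase A, had a peak from 9698808 to 9700008 on 2L with a signal of 6234. *Ubc6* (FBgn0004436), a ubiquitin-conjugating enzyme, had one from 4952402 to 4953038 on 3R with a signal of 5993. The peaks at *Jasper* (FBgn0039743, 30052199 to 30052959 on 3R) and at *Cpr* (FBgn0015623, the cytochrome P450 reductase, 6343361 to 6343988 on 2L) had signals of 5892 and 5360. CG10874 (FBgn0031395, 2192063 to 2192823 on 2L), the sorting nexin gene *Snx27* (FBgn0052758, 5737802 to 5738376 on X) and CG7137 (FBgn0034422, 19226977 to 19227664 on 2R) followed with 5322, 5142 and 5016. Replicate 1 gave *ush* a signal of 4225 and replicate 2 gave 5279, each the highest of its own list.

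Because *her* acts in sex determination, binding on the X chromosome was compared with that on the autosomes. X held 673 of the 3930 summits (17.1%, exact 95% interval 16.0 to 18.3), against 17.6% of the length of the main arms (exact binomial p = 0.463, two-sided). Peak density was 28.6 per Mb on X, between 26.7 on 3L and 32.7 on 2L. Chromosome 4 held 15 summits, 0.379 of the number its length predicts (p = 1.36e-05, exact binomial). For the 1965 peaks with the highest signal that ratio was 0.657 and the exact test did not pass (p = 0.141). At the level of genes, 467 of 2196 protein-coding genes on X (21.3%) had a summit within 1 kb of a TSS, against 2787 of 11749 (23.7%) on the autosomes. The odds ratio was 0.869 (95% interval 0.778 to 0.97, p = 0.0124, Fisher's exact test, two-sided). The embryos were of both sexes, so X was present in fewer copies than the autosomes. Whether that lowered the share on X was not tested. The odds ratio was 0.999 (Fisher's exact p = 1.0) for the 7860 strongest regions of the pooled relaxed list and 0.962 (Fisher's exact p = 0.485) when summits anywhere in the gene body or 1 kb upstream counted, so the lower share on X was not kept under either choice.

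*her* itself carried a thresholded peak at its promoter. The gene (2L, 16677185 to 16679691, plus strand) had a peak from 16676938 to 16677341 with the summit at 16677140, 45 bp upstream of the TSS, and a signal of 116 at rank 2686. As the tagged line carries additional *her* sequence, signal from added copies was not separated from binding at the native promoter. Of the 19 matched genes of the sex determination list, 9 were bound, *her* included, where matched random lists gave 29.3% of members. That difference did not pass (ratio 1.61, permutation p = 0.109, adjusted p = 0.201). The strongest of the 9 was *gro*, which encodes the Groucho corepressor (3R, summit 26042530, signal 461), followed by *ix*, a cofactor of the Doublesex protein (2R, 11360143, signal 327), and *emc*, which encodes an HLH inhibitor (3L, 749445, signal 245). *Sxl*, the master switch of the pathway, had a promoter summit at 7096668 on X, 398 bp from a TSS, with a signal of 185. *fru* (3R, 18439502, signal 147) was bound in an intron 731 bp from a TSS. *da* (2L, 10388048, signal 134), *snf* (X, 5309190, signal 127) and *fl(2)d* (2R, 13824733, signal 94.4) were bound at promoters. No thresholded summit lay within 1 kb of a TSS of *tra*, *tra2*, *dsx*, *sc*, *sisA*, *upd1*, *run*, *dpn*, *nito* or *vir*. None of the 3 yolk protein genes *Yp1*, *Yp2* and *Yp3*, the textbook targets of *dsx*, was bound (adjusted permutation p = 0.728). Of 9 dosage compensation genes, 2 were bound: *JIL-1*, a histone kinase, in its 5' UTR (3L, 11092445, signal 160 at rank 1514) and the RNA gene *lncRNA:roX1* in an exon (X, 3861389, signal 94.2). *msl-1*, *msl-2*, *msl-3*, *mle*, *mof*, *Clamp* and *lncRNA:roX2* were not, and the list did not pass against random lists (ratio 0.755, adjusted permutation p = 0.878). Its ratio was 0.379 without replicate 1 and 1.17 with the 7860 strongest pooled regions.

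Across the genome, 3254 of 13945 protein-coding genes (23.3%) had a thresholded summit within 1 kb of a TSS. Among the 37 gene lists, cytoplasmic ribosomal protein genes stood apart. Of 80 matched members 66 were bound (82.5%), against 26.6% in random lists matched on gene length and TSS number, a ratio of 3.10 (permutation p = 0.0001, the smallest that 10000 random lists can give, adjusted p = 0.0037). The strongest were *RpL8* (3L, summit 2586602, 854 bp from the TSS, signal 2358), *RpL7* (2L, 10201028, 24 bp, signal 824), *RpS27* (3R, 25247523, 9 bp, signal 712) and *RpL14* (3L, 8600985, 21 bp, signal 577). No other list passed the adjustment over the 37 lists in either direction. A summit within 1 kb can lie nearer the TSS of a neighbouring gene, and 1 summit can count for both genes of a divergent pair. The random lists were not matched on expression or promoter activity, and no untagged sample was analysed here. The excess at ribosomal protein genes can therefore not be assigned to the tagged protein.

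Among the thresholded peaks, the other lists of general cell functions lay above their expectation without passing. Translation factors had 10 of 18 members bound (adjusted permutation p = 0.175), led by *eEF1gamma* (signal 421), *pAbp* (signal 268), *eEF2* (signal 251) and *eEF1alpha1* (signal 208). The proteasome list had 12 of 32 (adjusted permutation p = 0.103), with *Rpn5* (signal 221), *Rpn3* (signal 162), *Rpt5* (signal 155) and *Rpn13* (signal 141). Mitochondrial respiration had 11 of 28 (adjusted permutation p = 0.167), with *COX5A* (signal 212), *ND-51* (signal 203), *COX6B* (signal 203) and *ATPsynF* (signal 184). Heat shock genes had 8 of 18 (adjusted permutation p = 0.177), with *Hsp83* (signal 557), *Hsp26* (signal 292), *Hsp27* (signal 231) and *lncRNA:Hsromega* (signal 154). Cell cycle and replication had 11 of 34 (adjusted permutation p = 0.878), with *dup* (signal 334), *Dp* (signal 312), *polo* (signal 190.0) and *Orc1* (signal 163). Genes for chromatin proteins were likewise above expectation without passing among the thresholded peaks. Insulator and architectural proteins had 9 of 15 bound (ratio 2.10), among them *Chro* (Chromator, signal 1339), *Trl* (the GAGA factor, signal 401), *Dref* (signal 295) and *BEAF-32* (signal 165). Polycomb and trithorax genes had 14 of 25 bound (ratio 1.73), with *ph-p* (signal 1185), *osa* (signal 952), *Trl* again and *Sfmbt* (signal 186). Both had an adjusted permutation p of 0.103. With the 7860 strongest pooled regions 3 of these lists passed above expectation (adjusted permutation p): mitochondrial respiration (23 of 28, ratio 2.09, p = 0.00185), proteasome (18 of 32, ratio 1.65, p = 0.0375) and Polycomb and trithorax (20 of 25, ratio 1.56, p = 0.0237). With unmatched random lists, translation factors (ratio 2.36), insulator proteins (2.57) and Polycomb and trithorax (2.41) passed. Among genes with a relaxed region within 1 kb of a TSS the ratios were 1.10 for mitochondrial respiration, 1.18 for the proteasome and 0.909 for the cell cycle.

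Among the thresholded peaks, members of most signalling pathways were bound more often than random lists, and no pathway passed the adjustment. Hippo and growth genes had 9 of 15 bound (ratio 1.92), with the kinase gene *wts* (signal 2056), *Mer* (signal 357), *yki* (signal 262) and *ds* (signal 256). The *yki* summit lay 575 bp from its own TSS, but within 500 bp of another gene's. Dpp and BMP genes also had 9 of 15 (ratio 1.82), with *shn* (signal 573), *Mad* (signal 376), *cv-2* (signal 143) and *Dad* (signal 109). Both had an adjusted permutation p of 0.103. EGFR and FGF genes had 9 of 15 (adjusted permutation p = 0.147), with *sty* (signal 776), *spi* (signal 323), *aop* (signal 226) and *Ras85D* (signal 205). E(spl) and Notch genes had 7 of 17 (adjusted permutation p = 0.119), with *numb* (signal 177), *N* (signal 146), *neur* (signal 126) and *E(spl)m3-HLH* (signal 119). Wnt and Hedgehog genes had 7 of 20, with *sgg* (signal 579), *Axn* (signal 204), *arr* (signal 131) and *Apc* (signal 119). The *Axn* summit likewise lay 733 bp from its own TSS, but within 500 bp of another gene's. JAK-STAT genes had 2 of 9, *Socs36E* (signal 147) and *Stat92E* (signal 117), and the ecdysone response 8 of 20, with *Eip75B* (signal 323), *E23* (signal 251), *usp* (signal 171) and *Hr38* (signal 126). The last 3 lists had ratios of 1.07, 0.794 and 0.96. Wnt and Hedgehog genes passed with the 7860 strongest pooled regions (18 of 20, ratio 1.75, adjusted permutation p = 0.0074), but without replicate 1 they had 5 of 20 (ratio 0.779) and in the 1965 strongest peaks 2 of 20 (ratio 0.562). Without replicate 1 the JAK-STAT ratio was 0.403. In the 1965 strongest peaks the ratio was 1.19 for E(spl) and Notch and 1.11 for Dpp and BMP. With unmatched random lists the Dpp and BMP (ratio 2.56), EGFR and FGF (2.57) and Hippo (2.58) lists passed (adjusted permutation p = 0.0169 each), and the ecdysone ratio was 1.71.

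**Figure D3:**
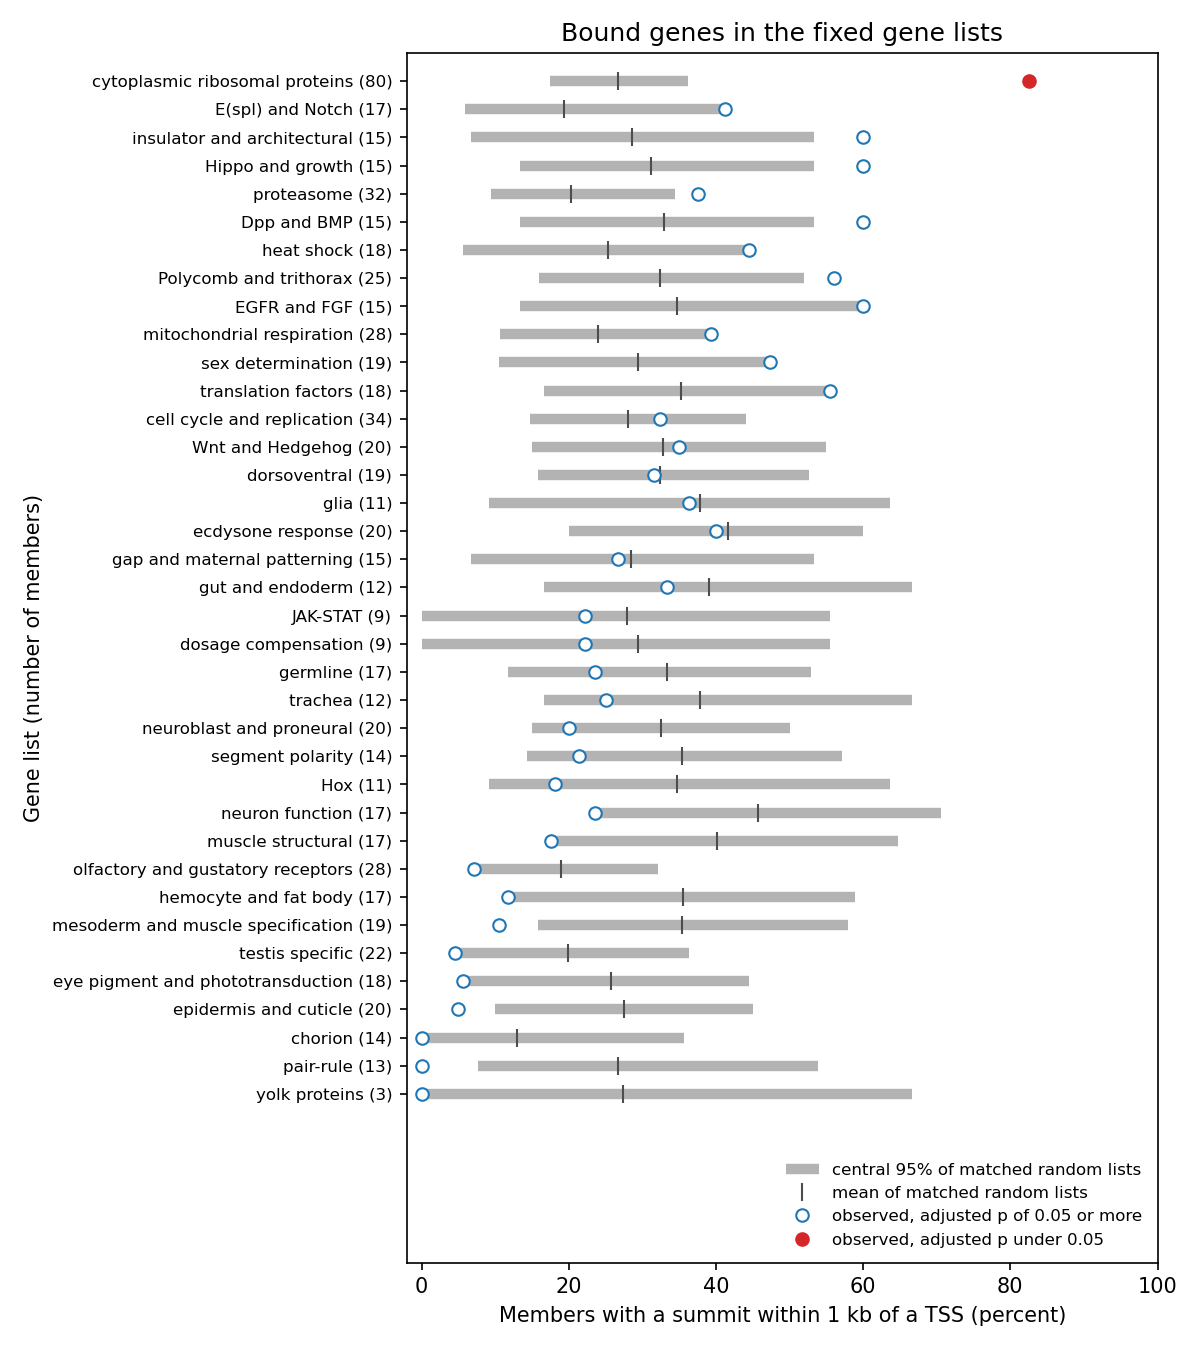
Percent of each list's members with a thresholded summit within 1 kb of a TSS (horizontal axis) for the 37 gene lists (vertical axis, number of members in brackets), with the mean and the central 95% of 10000 matched random lists. The filled point, at 82.5%, is the cytoplasmic ribosomal protein list, and the 36 open points have an adjusted p of 0.05 or more.

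Among the thresholded peaks, patterning and tissue lists lay mostly below the random share, without passing the adjustment. Of 13 pair-rule genes none was bound (unadjusted permutation p = 0.0472, adjusted 0.147), but 2 of 13 were without replicate 2 (unadjusted permutation p = 0.528) and 3 of 13 with the 7860 strongest pooled regions. Mesoderm and muscle specification had 2 of 19, *Mef2* (signal 136) and *pyr* (signal 119.7), at a ratio of 0.297 (adjusted permutation p = 0.103). Epidermis and cuticle had 1 of 20, *vvl* (signal 109), at a ratio of 0.182 (adjusted permutation p = 0.103). Hemocyte and fat body had 2 of 17, *ush* and *Adh* (signal 109), and muscle structural genes 3 of 17, *Msp300* (signal 491), *sls* (signal 282) and *Tm1* (signal 137), at ratios of 0.331 and 0.439. Neuron function had 4 of 17, with *elav* (signal 414), *Csp* (signal 109.8), *Syx1A* (signal 108) and *Nrg* (signal 94.9). Neuroblast and proneural genes had 4 of 20, namely *brat* (signal 358), *SoxN* (signal 122), *pros* (signal 109.8) and *nerfin-1* (signal 94.4). Glia had 4 of 11, namely *moody* (signal 861), *Gs2* (signal 349), *pnt* (signal 124) and *loco* (signal 120.1). Gut and endoderm had 4 of 12, namely *fkh* (signal 372), *cad* (signal 129), *pnt* and *Ance* (signal 92.9). Trachea had 3 of 12, namely *bnl* (signal 182), *sima* (signal 111) and *vvl*. Among axis and segment lists, gap and maternal patterning had 4 of 15 bound, with *cnc* (signal 176), *bcd* (signal 176), *cad* and *oc* (signal 97.5). Dorsoventral genes had 6 of 19, with *ush*, *rho* (signal 126), *brk* (signal 104) and *tup* (signal 93.1). Segment polarity had 3 of 14, *nkd* (signal 141), *smo* (signal 107) and *fz2* (signal 95.9), and Hox 2 of 11, *bcd* and *Antp* (signal 108). Germline genes had 4 of 17 bound, namely *Pxt* (signal 952), *bgcn* (signal 311), *tud* (signal 188) and *vas* (signal 108). The *Pxt* summit, 880 bp from its TSS, is the one that counts for *osa*. The summits counted for *vas* and, below, for *Or88a* lay 868 and 780 bp from their own TSS, but within 500 bp of another gene's. With the 7860 strongest pooled regions muscle structural genes (3 of 17, ratio 0.30, adjusted permutation p = 0.0074) and epidermis and cuticle (3 of 20, ratio 0.351, adjusted permutation p = 0.0375) passed below expectation, and segment polarity lay above it (9 of 14, ratio 1.18). Neuron function passed below without replicate 1 (1 of 17, ratio 0.133, adjusted permutation p = 0.0185). Without replicate 2 the ratios were 1.07 for germline, 0.489 for dorsoventral and 0.371 for epidermis and cuticle, against 0.705, 0.974 and 0.182. With unmatched random lists germline, gap, dorsoventral, neuron function, glia, trachea and gut had ratios from 1.00 to 1.57, so their place below rests on the matching. Lists of genes used mainly in the ovary, testis, eye and sense organs had few bound members, where random lists gave 13.0% to 25.8%: 0 of 14 chorion genes, 1 of 22 testis-specific genes (*bol*, signal 139.8), 2 of 28 odorant and taste receptor genes (*Or88a*, signal 193, and *Gr63a*, signal 126) and 1 of 18 eye pigment and phototransduction genes (*Rh5*, signal 213). Their adjusted permutation p values lay between 0.147 and 0.41. Most of these genes have no relaxed region near a TSS. Among those that do, 2 of 5 receptor genes (ratio 1.27), 1 of 4 testis genes (0.622) and 1 of 4 eye genes (0.572) were bound, and without replicate 1 the eye ratio was 0.43, against 0.216.

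Sequences known from housekeeping promoters were more frequent under the summits than beside them. Within 50 bp of the summit, TATCGATA, the DNA replication-related element, occurred at 143 of 3930 summits (3.64%) against 18 (0.458%) in an equally wide window 350 bp to the left (adjusted exact p = 9.54e-25). GGTCACAC, a core promoter element, occurred at 2.52% against 0.382% (adjusted exact p = 7.17e-16), and ATCGAT at 8.78% against 2.90% (adjusted exact p = 2.11e-27). CAGCTG, an E-box, was at 6.51% against 4.58% (adjusted exact p = 0.000584) and its longer form CAGCTGTT at 2.54% against 1.02% (adjusted p = 1.35e-06). AACAGCTG is the reverse complement of CAGCTGTT and carries the same values, so the 6 higher sequences on the list of 20 stand for 5 different ones. Of these, ATCGAT is part of TATCGATA and CAGCTG is part of CAGCTGTT, so their results are not independent. CACACA (9.08% against 12.2%), TATAAA (10.3% against 12.7%) and TAATTA (4.81% against 6.03%) were lower. GAGAG, the GAGA factor site, at 15.7% against 14.5% (adjusted exact p = 0.254), and CAGGTA, the Zelda site, at 1.96% against 2.42% (adjusted p = 0.316), did not pass. With the 7860 strongest pooled regions GAGAG was higher (16.1% against 13.7%, adjusted exact p = 7.2e-05), as was GAGAGAG (adjusted exact p = 0.0145). In the 1965 strongest peaks GAGAG did not pass and lay lower (log2 ratio -0.21), and GAGAGAG passed as lower (-0.70, adjusted exact p = 0.0422). All p values are from exact McNemar tests, two-sided, adjusted over the list alone. Of all 6-mers, tested as a separate family, 196 were higher at the summit and 211 lower, led by TATCGA (11.6% against 3.74%), CGATAG (9.31% against 2.90%) and ACACTG (11.4% against 4.35%). Among the 1438 summits over 500 bp from any TSS, none of the 20 listed sequences was higher after adjustment. Against the relaxed regions outside the thresholded peaks CAGCTG was not higher (6.51% against 6.72%, adjusted Fisher's exact p = 0.728), CACACA was lower without passing (log2 ratio -0.13, adjusted exact p = 0.122), and TATAAA and TAATTA were higher rather than lower. CAGCTG also did not pass within 25 bp of the summit (adjusted exact p = 0.0804), and CACACA did not with 7860 pooled regions (adjusted exact p = 0.129). Without replicate 2, TATAAA (log2 ratio -0.15, adjusted exact p = 0.181) and TAATTA (log2 ratio -0.30, adjusted exact p = 0.0683) did not pass, nor did they in the 1965 strongest peaks. TAATTA did not pass within 25 bp either.

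The tagged line carries additional *her* sequence, so the relaxed regions around the native gene were counted. The 40 kb window centred on *her* held 12 regions of the pooled list, against a median of 13 in windows at 2656 other protein-coding genes on 2L, which placed it at percentile 47.5. With 10 kb each side it held 10 against 6 (percentile 72.9), and with 50 kb 41 against 28 (percentile 70.7). By number it lay at percentile 49.2 in replicate 1 and 47.1 in replicate 2. By strength it stood higher: the median signal rank of its regions, 5710 to the nearest whole rank, was stronger than in 96.1% of the other windows in the pooled list, in 81.9% in replicate 1 and in 86.2% in replicate 2. No test was applied to these percentiles, which describe a place in a distribution.

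On dm3 X and chromosome 4 held nearly the same share of the peaks as on dm6. The dm3 lists hold 4390 thresholded peaks, 1.12 times the dm6 number. X held 750 (17.1%) on dm3 and 673 (17.1%) on dm6. Chromosome 4 held 17 and 15, and 3R, the arm with the most peaks, 1015 and 914. No coordinate was converted between builds and no test was made.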

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

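This part holds counts only, and no test was chosen after a result was seen. The dm3 relaxed lists hold regions outside the main chromosome arms of that build. No coordinate was converted, so whether the dm6 arms used above hold the same sequence was not determined. There were 14 such regions in the list of both replicates together, 12 in that of replicate 1 and 14 in that of replicate 2, each above the limit of 3 that a count of 0 allows. In the pooled list, 7 lay on XHet, 3 on 3RHet, 2 on U and 2 on Uextra, which are heterochromatic and unplaced sequences of that build. The strongest, on 3RHet, had a signal of 75.5 at rank 5111, below the lowest thresholded dm3 signal of 83.7. None of them was in the thresholded dm3 list, and no region of the dm6 lists lay outside the main arms. No explanation was tested.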

How the results depend on the processing

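No alternative was chosen after a result was seen. Over 77 results the alternatives gave 586 values, of which 521 kept their side of the threshold with no called direction turned or, for counts, stayed within 1.5 times. Results that passed under neither choice count among the 521. The main results were the arms, X genes, promoters, ribosomal proteins, replicate overlap, *her* windows and the numbers of lists and sequences called. Of their values 69 were kept, 15 counts did not stay within 1.5 times and 7 no longer passed their threshold. Lists that pass under neither choice can still move to the other side of 1. The promoter excess ran from 2.03- to 8.42-fold and the ratio of ribosomal protein genes from 2.19 to 4.10, and both passed under every alternative. Replicate overlap at 4000 regions ran from 68.4% to 77.3%, and the X share of summits passed under none. The call for chromosome 4 was lost in the 1965 strongest peaks (ratio 0.657). The lower odds on X were lost with 7860 pooled regions (0.999) and with gene bodies (0.962). Bound genes numbered 1784 with the 1965 strongest peaks and 5285 with 7860 pooled regions. With the latter 5 lists were above (ribosomal proteins, Wnt and Hedgehog, mitochondrial respiration, proteasome, Polycomb and trithorax) and 2 below expectation (muscle structural, epidermis and cuticle). With unmatched random lists 7 were above (ribosomal proteins, Dpp and BMP, EGFR and FGF, Hippo, translation factors, insulator, Polycomb and trithorax). Leaving out 1 replicate gave 0 to 1 lists below, the 1 being neuron function in replicate 2's list (ratio 0.133), and 1 to 3 listed sequences lower. Far from any TSS 0 listed sequences were higher and 1 lower. Counts of 6-mers, higher and lower, were 128 and 133 in the 1965 strongest peaks, 98 and 96 far from any TSS (fewer summits in both), 76 and 88 with 25 bp windows, and 520 and 654 against the 25123 other relaxed regions. For *her*, the share of windows with weaker regions was 93.9% at 10 kb each side, 74.0% at 50 kb and 81.9% to 86.2% without 1 replicate, all under 95%. Some listed sequences turned direction, as log2 ratios. Against other relaxed regions CAGCTG was at -0.041, TAATTA at 0.34, TATAAA at 0.48 and CCGGAA at -0.44. Far from any TSS CAGCTG was at -0.12, TATAAA at 0.034, and AACAGCTG and CAGCTGTT both at -0.22. GAGAGAG was at -0.70 in the 1965 strongest peaks. What caused these changes was not tested, also where an alternative held fewer summits. The dm3 counts per arm gave no test, because no dm3 arm lengths were used here. Depth is unknown, so weak and absent binding could not be told apart.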

Other observations

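The count of regions around *her* and their median signal rank were planned as descriptions. Reading the rank as a test of added copies was chosen after it was seen. The promoter comparison of the gapped sequence below rank 60 was set out after the sequence was read but before its own result. All other tests in this part were chosen only after the result was seen.

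Peaks of different strength sat differently on promoters. In the 393 strongest thresholded peaks, 277 summits lay at promoters, a median of 81 bp upstream of the TSS, and 81.2% of these were upstream. In the 393 weakest, 221 lay at promoters, a median of 22 bp upstream, and 58.4% were upstream. The 100 bp around the summit had a mean GC content of 38.8% in the strongest 393 and 41.7% in the weakest. The median region width was 338 bp in the strongest 393, and 226 and 196 bp in the next pair of groups of 393. It was the same value, 404 bp, in every weaker group and in the whole thresholded list. That repeated value was not taken as a measured width, so no trend of width with strength was read from these medians.

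A gapped sequence, CTCANNNNTGCG, lay within 50 bp of 24 of the 60 strongest summits (exact 95% interval 27.6% to 53.5%) and in 0 of their flanks on either side. It was read by eye in those 60, after several other sequences and 6-mer counts in up to the 400 strongest peaks had been looked at, so the 60 give no independent test. Of the 10 strongest peaks 7 carried it: at *ush* as CTCATAATTGCG (2L, 490307 to 490318), at CG2790 as CTCACAGATGCG, at *Pka-C1* as CTCACACCTGCG, at *Cpr* as CTCAAAAATGCG, at CG10874 as CTCACACTTGCG, at *Snx27* as CTCATATTTGCG and at CG7137 as CTCAGAAATGCG. Among the 3870 other summits, spacers of 1 to 8 bases gave 8, 8, 12, 22, 10, 7, 7 and 14 summits, against 6, 12, 6, 5, 9, 5, 7 and 7 left flanks. The genome holds 2401 copies, of which 48 lay within 50 bp of a thresholded summit. At promoters, 40 of 335 copies did.

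In the 60 strongest, base composition of the windows is an unlikely source. Of all sequences of 4 bases, 1 to 8 free bases and 4 bases, CTCANNNNTGCG was the commonest, in 24 windows. With the bases of each window shuffled 1000 times the commonest such sequence lay in at most 8 windows, and in 1000 draws of 60 promoter windows from other relaxed regions in at most 13 (permutation p = 0.001 for both, the smallest possible). The shuffles keep the bases of a window but not their order. This family of sequences was chosen after the sequence was read in the same windows, so the p values do not count the other sequences looked at. At promoters 23 of 52 of these summits carried it.

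A preference of the immunoprecipitated protein for the sequence is a hypothesis that the tables leave open. Among the 3870 summits ranked below 60, 22 carried it against 5 in the left flank (exact McNemar p = 0.00151), with 10 of them at ranks 61 to 393. At promoters 16 of 2440 thresholded summits ranked below 60 carried it, and 16 of 7853 in relaxed regions outside the peaks (Fisher's exact p = 0.00125). Past rank 400, beyond the peaks looked at beforehand, neither passed (12 against 5, exact McNemar p = 0.143; 9 of 2214 promoter summits, Fisher's exact p = 0.0945), so at these lower ranks base composition of promoters stays open too. A different protein bound at the same promoters, and recovery by the antibody without the tag, stay open, since no untagged sample was analysed here.

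More summits with the sequence stood higher in replicate 2 than in replicate 1, by rank among the 3914 peaks matched in both. Among the 400 strongest peaks this held for 23 of 34 summits with the sequence and for 26 of 65 summits without it that were nearest in rank. Fisher's exact p over summits was 0.0113, but each replicate is 1 library and these are the summits in which the pattern was seen, so position in the ranking alone stays open. Summits with the sequence also had more GC (44.5% against 39.9%) and lay more often at promoters (88.2% against 81.5%), and of all 400 those higher in replicate 2 were at promoters in 75.3%, against 64.3% of those higher in replicate 1. GC content and promoter location were not separated from the sequence, and no biological explanation was tested, because the design holds 1 group.

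Additional copies of *her* in the tagged line were weighed as a source of the regions around the native gene. The number of regions in the 40 kb window lay at percentile 47.5, and at 72.9 and 70.7 with 10 and 50 kb each side. All were under the 95 set for this count, so no excess of regions was found. The count takes no account of signal, so it cannot decide whether added copies raised the signal there. The strength of the regions leaves this open too. Their median rank was stronger than in 96.1% of other windows in the pooled list with 20 kb each side. With 10 kb and 50 kb each side the share was 93.9% and 74.0%, and it was not above 95% in either replicate. Whether copies raise the signal there cannot be told apart from binding near *her* in these lists. Only the pooled list with 20 kb each side passes, and no untagged sample was analysed here.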
